A study of Rattus norvegicus with 34 samples.

How the data were processed

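Testis RNA of 34 male Wistar Han rats was labelled in the series, 1 Affymetrix rat genome array per animal, and 31 arrays held values. The animals had received myclobutanil, propiconazole or triadimefon, which are triazole fungicides, in the diet from gestation day 6 to postnatal day 92. The other 3 arrays (Control replicate 01, M500 replicate 03 and T1800 replicate 01) are marked in the labels as left out of the final analysis, and they were not analysed here. The groups analysed were Control (0 ppm, 6 arrays), M500 (myclobutanil 500 ppm, 3), M2000 (myclobutanil 2000 ppm, 5), P500 (propiconazole 500 ppm, 4), P2500 (propiconazole 2500 ppm, 5), T500 (triadimefon 500 ppm, 4) and T1800 (triadimefon 1800 ppm, 4). Group and replicate were taken from the labels. Each array stands for 1 animal by its animal number. The litters of the animals were not given in the sources used here, and animals of 1 litter would not be independent.

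Per the labels' protocols, RNA was extracted with TRI Reagent, treated with DNase, cleaned on RNeasy columns, checked on a Bioanalyzer, copied from an oligo-dT primer and labelled as biotin cRNA. Those protocols cover liver as well as testis RNA of the study. The values deposited by the authors are a score per probe set, on a log-like scale with every array centred near a median of 0 (array medians -0.00914 to 0.0558). How the authors summarised the probes, corrected background and normalized is not given in the sources used here. The scores of the 4 hybridisation controls rose about evenly with the log of their concentration, but their slope per doubling ran from 0.432 to 0.939 between arrays (median 0.473). Neither the base of the logarithm nor a common gain of the arrays is therefore known, so differences are given in score units and never as folds. On the deposited scores, 6.28% to 17.7% of an array's probe sets lay above bioB, the hybridisation control of lowest concentration. Most probe sets, including many of the genes named below, thus measured under that control. For arrays, their number per group limits the precision, and the median standard error of a difference with control ran from 0.033 to 0.038 score units over the 6 groups.

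The design fixed before the data were examined assumed log2 values used as deposited. Since the values were scores of unequal gain, the arrays were quantile normalized with limma before any call was seen, and the scores as deposited became an added alternative. The table held 31099 probe sets. Of these, 57 control probe sets were left out and 31042 were tested. The platform annotation, which can be old, paired 20826 with 1 gene symbol, 436 with several and 9780 with none, giving 14217 genes. No gene was named from a probe set with several symbols, so Hsd3b2 was not reported.

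Tests were made in R 4.3.3 with limma 3.58.1. One linear model with a mean per group was fitted over all 31 arrays with equal weights (lmFit, eBayes), so that the 7 groups shared 1 estimate of the spread, and 16 contrasts were tested. These were each exposed group against control, the mean of the 3 high-dose groups against control, the compounds against each other at 500 ppm and at their high doses, and high against mid dose of each compound. P-values were adjusted by Benjamini-Hochberg over the 31042 probe sets of a contrast, with 0.05 as the threshold, and all adjusted p-values are limma's.

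The 21 gene lists, fixed before the data were examined, were cholesterol biosynthesis and uptake, steroidogenesis, xenobiotic metabolism and transport, retinoic acid metabolism and signalling, fatty acid oxidation, NRF2 and antioxidant response, endoplasmic reticulum stress, heat shock and immediate early genes, p53 response and apoptosis, androgen-responsive Sertoli genes, and markers of Sertoli cells, spermatogonia, spermatocytes, spermatids, peritubular and smooth muscle cells, macrophages, endothelium, fibroblasts and matrix, erythrocytes, epididymis and adipocytes. Each list was tested in the 7 contrasts with control by limma's camera with a preset correlation of 0.01, with 1 probe set per gene (highest mean), and adjusted over the 147 tests. Camera with an estimated correlation and fry were run beside it. Mean shifts of a list came from a limma fit to the mean of its genes per array. The value shown for a list member came from that gene's probe set with the smallest p, and the ranges over groups of the genes always taken came from the probe set of highest mean.

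Genes were named by a rule fixed before the data were examined. Of probe sets past the threshold it took up to 10 genes in each direction. Where fewer than 5 passed it took the 3 genes with the smallest p in each direction, and for a described list up to 4 members with the smallest p. Values of 10 further genes were always taken: Cyp51, Star, Cyp11a1, Hsd3b1 or Hsd3b2, Cyp17a1, Hsd17b3, Insl3, Lhcgr, Por and Cyp26b1.

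RNA quality was measured as the score of the 3' minus that of the 5' beta-actin control probe set (the actin gap), and 52 liver markers were listed for a test of liver transcripts. Labels also give animal numbers: Control replicates 05 to 07 and T1800 replicates 03 to 05 belonged to a later series of numbers, and all other arrays to an earlier series. Array pairs were compared before averaging. The closest 2, Control replicates 05 and 07, had a root mean square difference of 0.0404, and no 2 arrays were identical.

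The steps were tested on simulated data. In 5 simulated data sets of T1800 against control with 31042 probe sets, 200 of them changed, the fit with equal weights recovered 77% of changes of 0.25 score units, 95.2% of 0.5 and 100% of 1, with 37 false among 944 calls. With limma's array weights it recovered 89.3%, 98.2% and 100%, with 5543 false among 6501 calls and 5439 of them in 1 data set. Array-weighted counts are therefore given as an alternative and do not lead. Camera found a list shifted by 0.2 in 5 of 5 data sets over 14217 genes, with 0 to 2 of the 20 other lists passing.

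Alternatives listed before the data were examined were array median centring, a filter on dim probe sets, trend and robust moderation, only the groups compared, array weights, blocks for replicate number and animal series, only animals of the earlier series, another rule for a gene's probe sets, other list tests, split controls and leaving out each array. Those added after seeing the data were the scores as deposited, scaling by the hybridisation controls, only animals of the later series, the actin gap as a covariate, leaving out the 5 arrays with a gap above 1.4, leaving out the 3 P2500 arrays with liver transcripts, and array weights for the lists. Fits with the actin and GAPDH gaps together, without 6 arrays, and with array weights and the actin gap together were looked at and not kept.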

Results

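Gene expression was measured in the testis of adult male rats that had eaten a diet with 1 of 3 triazole fungicides from gestation day 6 to postnatal day 92, or a diet without it. The 3 compounds share a triazole ring and differ in the rest of the molecule: myclobutanil carries a nitrile, propiconazole a dioxolane ring and a dichlorophenyl group, and triadimefon a ketone and a chlorophenoxy group. Triazoles inhibit the fungal sterol demethylase Cyp51 and can act on mammalian cytochrome P450 enzymes, including those that make steroids. There were 6 control arrays, 3 at 500 ppm and 5 at 2000 ppm of myclobutanil (M500, M2000), 4 at 500 ppm and 5 at 2500 ppm of propiconazole (P500, P2500), and 4 at 500 ppm and 4 at 1800 ppm of triadimefon (T500, T1800). All values are quantile-normalized scores, and all differences are in score units.

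The arrays differed most along 1 component, which held 49.9% of the variance. The actin gap, a measure of RNA quality in which a larger gap means less of the 5' end, was 1.12 ± 0.408 (SD, n = 6) in control, 1.08 ± 0.455 (n = 3) in M500, 0.994 ± 0.272 (n = 5) in M2000, 1.14 ± 0.213 (n = 4) in P500 and 1.02 ± 0.287 (n = 5) in P2500. It was 0.79 ± 0.0748 (n = 4) in T500 and 0.852 ± 0.0529 (n = 4) in T1800. It exceeded 1.4 in 5 arrays: Control replicates 02 (1.67) and 06 (1.63), M500 replicate 04 (1.6), M2000 replicate 05 (1.47) and P2500 replicate 05 (1.47).

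After triadimefon at 1800 ppm, 2 genes were higher than in control. Arhgef28, a guanine nucleotide exchange factor, was 0.751 ± 0.18 (SD, n = 4) in T1800 and 0.308 ± 0.077 (n = 6) in control, a difference of 0.44 (SE 0.074, adjusted p = 0.033). S100b, a calcium-binding protein, was 0.457 ± 0.087 (n = 4) against 0.205 ± 0.041 (n = 6), a difference of 0.25 (SE 0.042, adjusted p = 0.033). Both lay above the control mean in 4 of 4 arrays. No probe set was lower, 1814 of 31042 had an unadjusted p under 0.05 where 1552 were expected by chance, and limma with array weights called 264. Arhgef28 also measured 0.707 ± 0.16 (n = 3) in M500, a difference from control of 0.399 that did not pass, while its second probe set differed by 0.001 in T1800. Among animals of the later number series (n = 3 and 3), Arhgef28 was 0.729 ± 0.21 against 0.361 ± 0.027 and S100b 0.436 ± 0.094 against 0.198 ± 0.047 (adjusted p = 0.82 for both). With a block for the animal series the difference of Arhgef28 was 0.433 (adjusted p = 0.074) and that of S100b 0.261 (0.036). Both calls ended with only the groups compared (differences 0.443 and 0.252, adjusted p = 0.28 and 0.27), with the scores as deposited (0.426 and 0.245, adjusted p = 0.2 and 0.051) and with the actin gap as a covariate (0.451 and 0.229, adjusted p = 0.076 for both). They also ended without the 5 arrays of actin gap above 1.4 (0.447 and 0.231, adjusted p = 0.12 for both) and without T1800 replicate 02 (0.422 and 0.232, adjusted p = 0.42 for both) or 04 (0.377 and 0.223, 0.58). The differences thus stayed of similar size while the adjusted p moved.

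**Figure D1:**
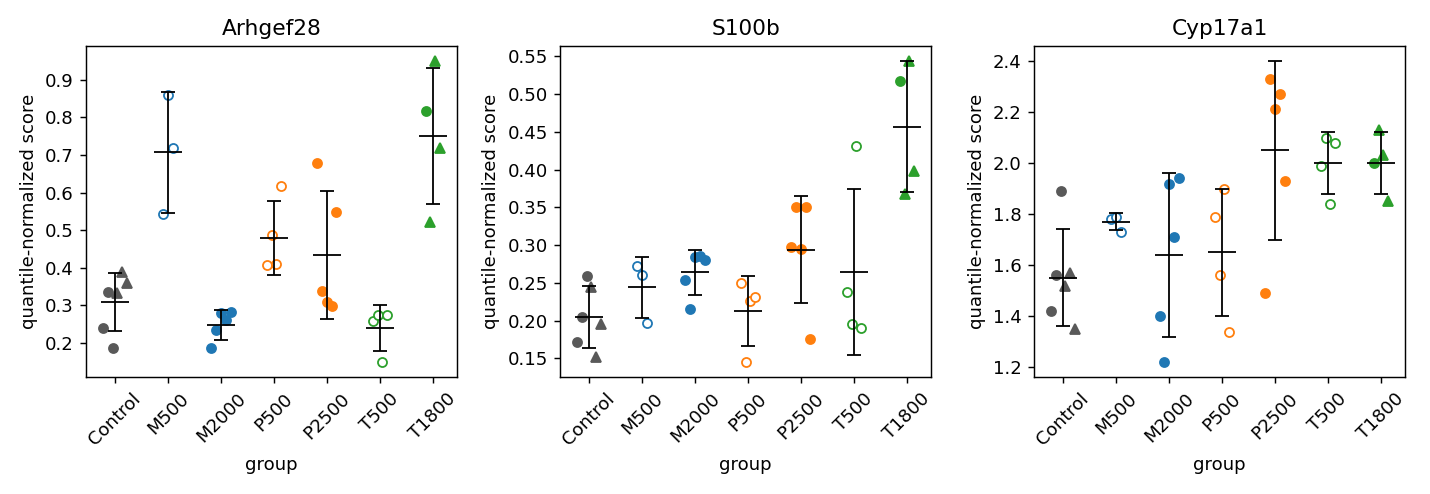
Quantile-normalized score (vertical axis, score units) of Arhgef28, S100b and Cyp17a1 in each array of the 7 groups (horizontal axis). Each point is 1 animal, triangles are animals of the later number series, open symbols mark 500 ppm, and bars give the mean and SD; the T1800 arrays lie between 0.521 and 0.95 for Arhgef28 against 0.188 to 0.388 in control.

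Among the fixed lists, 3 rose in T1800 by camera. Fibroblast and matrix genes shifted by 0.21 (SE 0.069, adjusted p = 0.00026, adjusted p = 0.37 with an estimated correlation). Of the 14 measured, 7 were higher when adjusted over the list alone and 0 over all probe sets. They included the proteoglycan decorin, Dcn, at 1.32 ± 0.038 (SD, n = 4) against 0.629 ± 0.12 (n = 6), as well as the collagen genes Col6a2 (0.245 ± 0.033 against 0.0716 ± 0.066) and Col1a1 (0.547 ± 0.15 against 0.216 ± 0.13). Macrophage genes shifted by 0.053 (SE 0.03, adjusted p = 0.00014, adjusted p = 0.37 with an estimated correlation), with 5 of 20 higher when adjusted over the list alone and 0 over all probe sets. Their shift was 0.024 with the actin gap as a covariate and 0.018 without the 5 arrays of actin gap above 1.4. The complement gene C1qa measured 0.244 ± 0.033 against 0.0789 ± 0.05, Cd74, an invariant chain of antigen presentation, 1.14 ± 0.078 against 0.913 ± 0.16, and lysozyme Lyz2 1.06 ± 0.035 against 0.854 ± 0.14.

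Genes of Leydig cell steroidogenesis shifted in T1800 by 0.099 (SE 0.04, adjusted p = 0.01, adjusted p = 0.5 with an estimated correlation), with 3 of 19 higher when adjusted over the list alone and 0 over all probe sets. Tspo, a mitochondrial protein tied to cholesterol import, measured 0.922 ± 0.12 (SD, n = 4) against 0.696 ± 0.11 (n = 6), and Insl3, a Leydig cell peptide hormone, 1.52 ± 0.082 against 1.04 ± 0.43. Cyp17a1, the steroid hydroxylase and lyase of androgen synthesis, measured 2 ± 0.12 against 1.55 ± 0.19. The actin gap of these arrays was 0.852 against 1.12 in control. Insl3 measured 0.518 and 0.465 in Control replicates 02 and 06, whose actin gaps were 1.67 and 1.63, and 1.202 to 1.35 in the other controls. Its low control mean thus rests on these 2 arrays. Within the later animal series (n = 3 and 3) the shifts were 0.21 for fibroblast and matrix, 0.051 for macrophage and 0.12 for steroidogenesis genes. The steroidogenesis call ended without T1800 replicate 04 (adjusted p = 0.059). Outside the passing genes, the smallest p was that of Cyp2g1, a cytochrome P450, on the higher side (0.42 ± 0.081 against 0.231 ± 0.077, adjusted p = 0.11). On the lower side stood Macroh2a2, a histone variant (0.303 ± 0.11 against 0.551 ± 0.037, adjusted p = 0.11), Perp (-0.188 ± 0.028 against -0.0669 ± 0.055; 0.2) and the acyl-CoA synthetase Acsl1 (1.61 ± 0.036 against 1.85 ± 0.13; 0.2).

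Propiconazole at 2500 ppm came with liver transcripts in 3 of 5 arrays. Albumin, Alb, measured 4.15, 3.89 and 3.91 in P2500 replicates 02, 03 and 04, 0.0616 and -0.124 in replicates 01 and 05, and 0.132 to 1.65 in the 6 control arrays. The protease inhibitor Serpina1 measured 2, 1.96 and 1.91 in those 3 arrays against 0.0156 to 0.387 in control, and the male-specific liver enzyme Cyp2c11 1.75, 1.75 and 1.68 against -0.217 to 0.0204. The plot of Alb and of the liver markers shows each array.

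**Figure D2:**
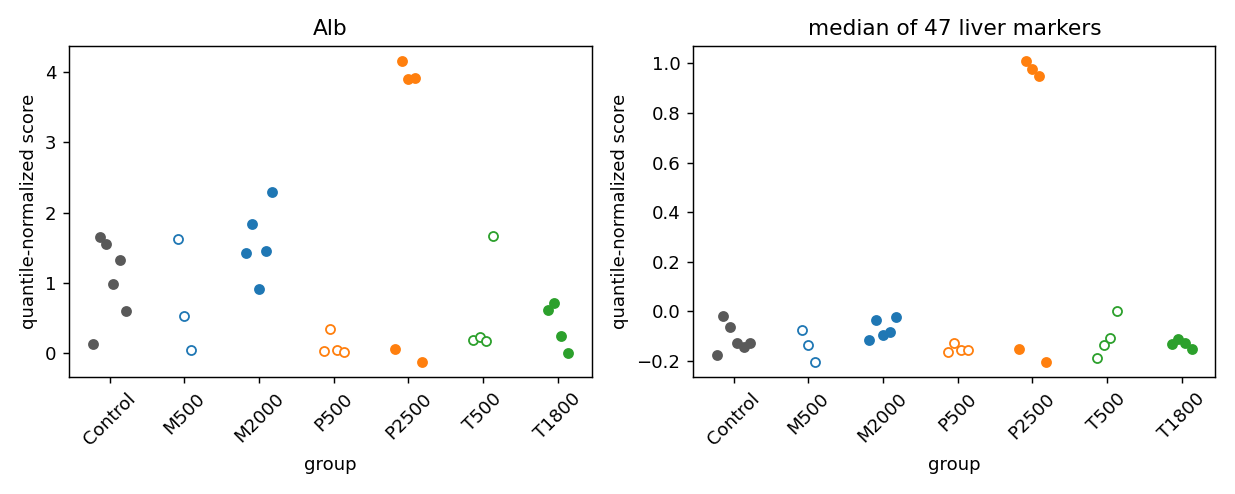
Score of Alb (left) and median score of the liver markers (right; vertical axes, score units) in each array of the 7 groups; each point is 1 animal. P2500 replicates 02, 03 and 04 lie at 3.89 to 4.15 for Alb and at 0.949 to 1.01 for the marker median, above all other arrays.

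Of the lists, 8 rose in P2500 by camera over all 5 arrays. Xenobiotic metabolism and transport shifted by 0.29 (SE 0.072, adjusted p = 2.2e-16, adjusted p = 0.12 with an estimated correlation), with 14 of 31 higher when adjusted over the list alone and 0 over all probe sets. Cyp2e1, an ethanol-inducible liver enzyme, measured 1.02, 0.942 and 0.911 in replicates 02 to 04 and -0.124 and 0.0161 in 01 and 05. Group values of Cyp3a23-3a1 were 0.58 ± 0.93 (SD, n = 5) against -0.37 ± 0.08 (n = 6), of the glucuronosyltransferase Ugt2b1 0.28 ± 0.45 against -0.201 ± 0.037, and of the transporter Abcc2 -0.233 ± 0.099 against -0.359 ± 0.021. Steroidogenesis shifted by 0.14 (SE 0.038, adjusted p = 1.1e-06, adjusted p = 0.16 with an estimated correlation), with 6 of 19 higher when adjusted over the list alone and 0 over all probe sets. Its leading members were Akr1c14 (-0.134 ± 0.2 against -0.363 ± 0.052), Hsd3b5 (0.0497 ± 0.25 against -0.193 ± 0.085), Cyb5a (0.854 ± 0.38 against 0.462 ± 0.13) and Cyp17a1 (2.05 ± 0.35 against 1.55 ± 0.19). Their SDs were larger in P2500 than in control. With liver transcripts in 3 of the 5 arrays, these group values cannot tell expression in testis from RNA of liver.

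Fatty acid oxidation shifted in P2500 by 0.051 (SE 0.02, adjusted p = 0.00026, adjusted p = 0.31 with an estimated correlation) with 4 of 24 genes higher when adjusted over the list alone and 0 over all probe sets. The thiolase Acaa2 was among them (1.31 ± 0.052, SD, n = 5, against 1.09 ± 0.14, n = 6). NRF2 and antioxidant genes shifted by 0.071 (SE 0.017, adjusted p = 0.0056, adjusted p = 0.11 with an estimated correlation), with 5 of 18 higher when adjusted over the list alone and 0 over all probe sets. Among them were catalase, Cat (0.929 ± 0.41 against 0.466 ± 0.11), and the quinone reductase Nqo1 (0.144 ± 0.06 against 0.0532 ± 0.042). The cholesterol list (0.029, SE 0.012, adjusted p = 0.015) and the fibroblast and matrix list (0.12, SE 0.065, 0.022) also passed with the preset correlation, with adjusted p = 0.31 and 0.55 with an estimated correlation. So did the epididymis list (0.088, SE 0.033, adjusted p = 0.00042) and the adipocyte list (0.058, SE 0.023, 0.014), with adjusted p = 0.12 and 0.34 with an estimated correlation. Adjusted over each list alone, 2, 1, 2 and 0 of their genes were higher and 1 matrix gene, Fbln1, lower (0.0766 ± 0.061 against 0.188 ± 0.067). Without P2500 replicates 02 to 04 none of the 8 lists passed, but only 2 P2500 arrays were left, 1 with an actin gap of 1.47. The shift was then -0.019 for xenobiotic metabolism (95% interval -0.11 to 0.069), -0.0066 for cholesterol (-0.03 to 0.017), -0.0076 for fatty acid oxidation (-0.052 to 0.037) and -0.016 for adipocyte genes (-0.064 to 0.033). These intervals lie below the point values of the shifts over all 5 arrays, as does that of NRF2 genes, barely (-0.011 to 0.068). For steroidogenesis (0.04, -0.056 to 0.14), matrix (-0.031, -0.21 to 0.14) and epididymis genes (0.03, -0.064 to 0.12) they reach them. The shifts over all 5 arrays have a spread of their own, and the arrays left are among those 5. Against both spreads the gap is clear for xenobiotic genes alone. For the other lists, lost calls cannot be separated from lost precision. The adjusted p-values were 0.43 for steroidogenesis, 0.28 for NRF2 and 0.13 for epididymis in the same direction, and 0.58 for xenobiotic metabolism, 0.9 for cholesterol, 0.89 for fatty acid oxidation, 0.38 for matrix and 0.76 for adipocyte genes in the opposite direction.

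No single probe set passed in P2500 with limma and equal weights (smallest adjusted p 0.073, 1289 at an unadjusted p under 0.05, 1552 expected), and array weights called 882. The genes of smallest p, which did not pass, were Apon (-0.369 ± 0.09, SD, n = 5, against -0.551 ± 0.049, n = 6), the paraoxonase Pon2 (0.279 ± 0.081 against 0.126 ± 0.039) and the mannosidase Man1a1 (0.22 ± 0.071 against 0.0631 ± 0.038) on the higher side. On the lower side they were Iqca1 (0.74 ± 0.12 against 1.08 ± 0.091), Fbxo41 (0.16 ± 0.011 against 0.256 ± 0.047) and Hmcn2 (0.129 ± 0.042 against 0.22 ± 0.039). Leaving out replicate 05 gave 283 calls, and leaving out replicates 02 to 04 together gave 0.

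After myclobutanil at 2000 ppm, spermatid markers were higher by camera (shift 0.047, SE 0.038, adjusted p = 0.029, adjusted p = 0.55 with an estimated correlation). Of the 25 genes measured, 0 passed adjusted over the list alone or over all probe sets. Smcp, a sperm mitochondrial protein, measured 4.29 ± 0.018 (SD, n = 5) against 4.18 ± 0.21 (n = 6), and Tssk2, a testis-specific kinase, 3.11 ± 0.025 against 3.05 ± 0.12. The list shifted in the opposite direction with the scores as deposited (adjusted p = 0.043) and with array weights (0.94). The call ended with the actin gap as a covariate (adjusted p = 0.22), without the 5 arrays of actin gap above 1.4 (0.81), without Control replicate 02 (0.44) or 06 (0.36), without M2000 replicate 01 (0.34), 02 (0.063) or 03 (0.054), and when adjusted over the 21 lists of this contrast. The actin gap was 0.994 in M2000 and 1.12 in control. No probe set passed with limma (smallest adjusted p 1, 528 at an unadjusted p under 0.05, 1552 expected), and array weights called 8. Smallest p belonged to Fgl2, a fibrinogen-like protein (0.646 ± 0.038 against 0.515 ± 0.054), Metap1 (1.22 ± 0.026 against 1.1 ± 0.081) and Slc66a1 on the higher side, and to the growth regulator Tsc1 (0.374 ± 0.026 against 0.47 ± 0.03), Chac2 and Tp63 on the lower side, all with adjusted p = 1.

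For the mean of the 3 high-dose groups, 6 lists rose by camera. Steroidogenesis shifted by 0.09 (SE 0.031, adjusted p = 0.00026), xenobiotic metabolism by 0.13 (SE 0.058, 7.7e-06) and fatty acid oxidation by 0.034 (SE 0.016, 0.014), with adjusted p = 0.34, 0.45 and 0.46 with an estimated correlation. Macrophage genes shifted by 0.033 (SE 0.023, adjusted p = 0.017), matrix genes by 0.11 (SE 0.052, 0.014) and epididymis genes by 0.054 (SE 0.027, 0.029), with adjusted p = 0.55, 0.55 and 0.34 with an estimated correlation. Of their members, 0 were higher when adjusted over the list alone or over all probe sets. Fbln1, a matrix glycoprotein, fell when adjusted over the list alone (0.0972 ± 0.051, SD, n = 14, against 0.188 ± 0.067, n = 6) and did not pass over all probe sets (adjusted p = 0.99). Without the 3 P2500 arrays with liver transcripts, steroidogenesis still passed (adjusted p = 0.049), and the others did not (0.37 for xenobiotic metabolism, fatty acid oxidation and matrix, 0.18 for macrophage and 0.21 for epididymis). No probe set passed with limma (smallest adjusted p 0.35, 1105 at an unadjusted p under 0.05), and array weights called 294. Smallest p belonged to Fgl2 (0.646 ± 0.052 against 0.515 ± 0.054), Hyi and Pon2 on the higher side and to Tp63, Fbxo41 and the potassium channel Kcna4 on the lower side.

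**Figure D3:**
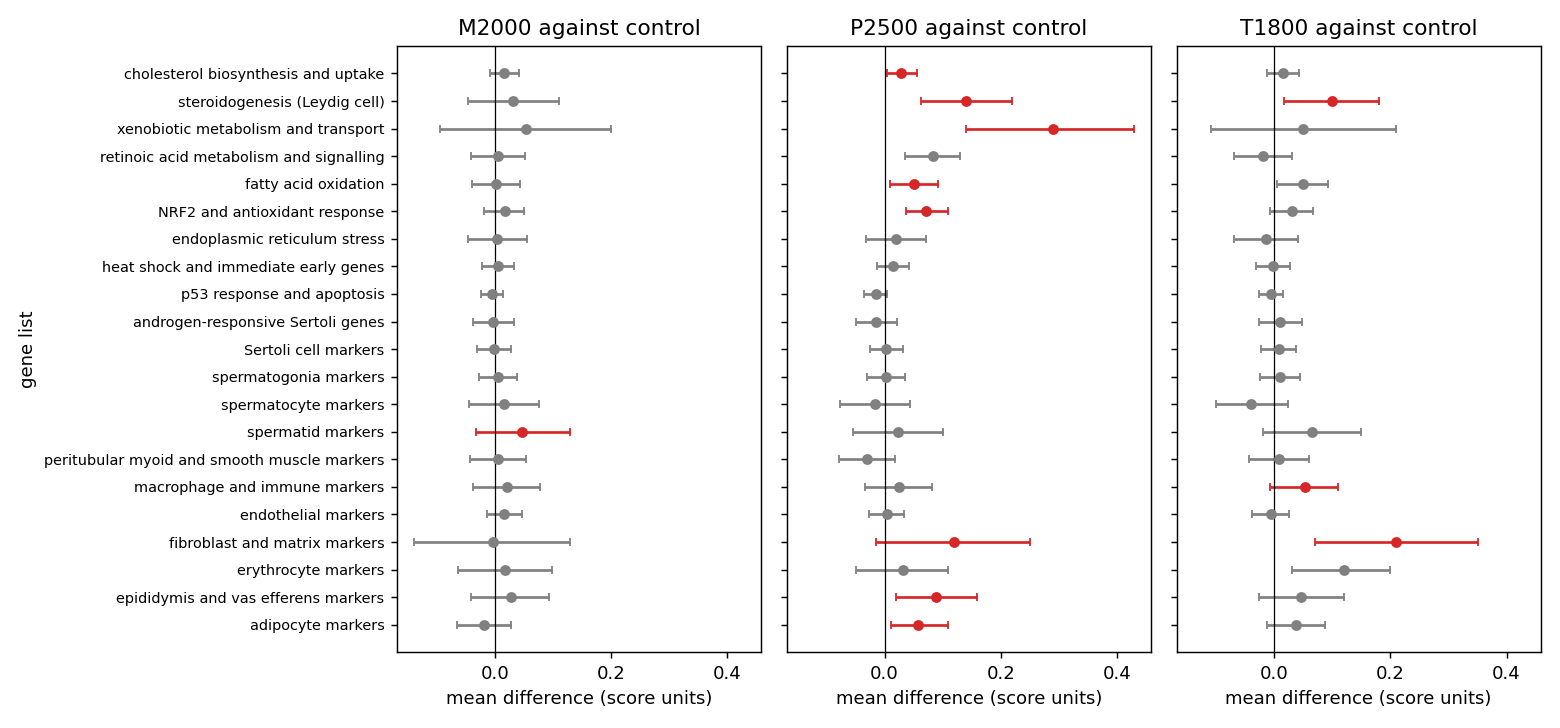
Mean difference from control (horizontal axis, score units) of the 21 gene lists (vertical axis) in M2000, P2500 and T1800; points are the mean over a list's genes, bars the 95% confidence interval, and red marks lists with a camera adjusted p under 0.05. The xenobiotic list in P2500 lies at 0.29 and the matrix list in T1800 at 0.21.

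After propiconazole at 500 ppm, peritubular and smooth muscle markers (shift -0.04, SE 0.025, adjusted p = 0.014) and fibroblast and matrix markers (-0.067, SE 0.069, 0.018) were lower by camera, and epididymis markers were higher (0.036, SE 0.035, 0.022). With an estimated correlation the adjusted p = 0.45, 0.55 and 0.34. Of the 12, 14 and 11 genes measured, 0 passed adjusted over the list alone or over all probe sets. Mylk, the myosin light chain kinase, measured 1.03 ± 0.093 (SD, n = 4) against 1.14 ± 0.16 (n = 6), the matrix protein Sparc 1.01 ± 0.12 against 1.15 ± 0.13, and the defensin Defb22 -0.126 ± 0.029 against -0.173 ± 0.02. The actin gap was 1.14 in P500 and 1.12 in control. Without Control replicate 02 the adjusted p-values were 0.11, 0.071 and 0.077, and without the 5 arrays of actin gap above 1.4 they were 0.13, 0.36 and 0.79. Without P500 replicate 04 the muscle (0.28) and matrix (0.15) calls ended, and without P500 replicate 01 (0.077) or 03 (0.085) the epididymis call. No probe set passed with limma (smallest adjusted p 0.96, 1042 at an unadjusted p under 0.05), and array weights called 17. Smallest p belonged to Gdpd1 (0.918 ± 0.067 against 0.783 ± 0.047), Arid4b and Nat10 on the higher side and to the mast cell protease Mcpt4 (-0.407 ± 0.035 against -0.311 ± 0.047), Acsl1 and Zbtb7a on the lower side.

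After myclobutanil at 500 ppm, epididymis markers were higher by camera (shift 0.063, SE 0.039, adjusted p = 0.029, adjusted p = 0.34 with an estimated correlation), with 0 of 11 genes passing adjusted over the list alone or over all probe sets. The water channels Aqp1 and Aqp9 measured 0.291 ± 0.021 (SD, n = 3) against 0.211 ± 0.074 (n = 6) and 1.17 ± 0.16 against 1.06 ± 0.072. The call ended without any 1 of M500 replicates 01 (adjusted p = 0.081), 02 (0.062) and 04 (0.18), Control replicate 02 (0.095) or Control replicate 06 (0.19), and when adjusted over the 21 lists of this contrast. No probe set passed with limma (smallest adjusted p 0.093, 2793 at an unadjusted p under 0.05), and array weights called 61. Leaving out M500 replicate 01 gave 156 calls. Smallest p belonged to the mitochondrial import protein Timm9 (0.968 ± 0.11 against 0.77 ± 0.057), Ppa1 (1.63 ± 0.023 against 1.44 ± 0.038) and the prostaglandin dehydrogenase Hpgd on the higher side, and to Gatad2a (1.16 ± 0.065 against 1.35 ± 0.026), the splicing factor Sf1 and Nrip3 on the lower side.

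In T500 no list passed by camera, 0 did with an estimated correlation or by fry, and no probe set passed with limma (smallest adjusted p 0.055, 2366 at an unadjusted p under 0.05, 44 with array weights). Fibroblast and matrix genes shifted by 0.13 (SE 0.069, adjusted p = 0.092), with Dcn at 1.19 ± 0.22 (SD, n = 4) against 0.629 ± 0.12 (n = 6). The actin gap was 0.79 in T500 and 1.12 in control. Smallest p belonged to the potassium channel Kcnd2 (0.729 ± 0.11 against 0.222 ± 0.13, adjusted p = 0.098), mrpl24 and Taldo1 on the higher side, and to the mitochondrial gene COX1 (4.03 ± 0.2 against 4.4 ± 0.042, adjusted p = 0.47), Lrrc71 and Gatad2a on the lower side.

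None of the genes always taken passed over all probe sets in any contrast with control with equal weights on all arrays. In P2500, Cyp17a1 passed without replicate 01 (difference 0.633, adjusted p = 0.0049) and Star without replicate 05 (0.456, 0.014) or without the 5 arrays of actin gap above 1.4 (0.412, 0.016). In each case 3 of the 4 P2500 arrays left carried liver transcripts, and Cyp17a1 measured 2.327, 2.211 and 2.269 in these and 1.488 and 1.933 in replicates 01 and 05. Star measured 1.185, 1.032 and 1.021 in these and 0.941 and 0.327 in replicates 01 and 05, against 0.398 to 0.818 in control. Star was thus also above every control in replicate 01, which lacked liver transcripts, and was low in replicate 05, of actin gap 1.47. With array weights Cyp17a1, Star and Hsd3b1 passed in P2500 (adjusted p = 0.00074, 0.00061 and 0.039), Cyp17a1 and Hsd17b3 in T1800 (0.038 and 0.028) and Cyp17a1 in the mean of the high doses (0.027). Differences of the 6 exposed groups from control are given on each gene's probe set of highest mean. For Cyp51 they ran from -0.17 (SE 0.13, T500) to 0.1 (SE 0.13, P500). Star, which carries cholesterol into mitochondria, ran from 0.01 (SE 0.13, T500) to 0.31 (SE 0.12, P2500), and Cyp11a1, the side-chain cleavage enzyme, from -0.1 (SE 0.11, P500) to 0.14 (SE 0.11, P2500; SE 0.13, M500). The dehydrogenase Hsd3b1 ran from -0.19 (SE 0.1, P500) to 0.21 (SE 0.098, P2500), Cyp17a1 from 0.085 (SE 0.14, M2000) to 0.49 (SE 0.14, P2500, adjusted p = 0.16), and Hsd17b3, which makes testosterone, from -0.013 (SE 0.023, M2000) to 0.077 (SE 0.025, T1800). Insl3 ran from 0.021 (SE 0.18, P500) to 0.48 (SE 0.18, T1800), and the luteinizing hormone receptor Lhcgr from -0.042 (SE 0.06, T1800) to 0.1 (SE 0.056, P2500). Values ran for the P450 reductase Por from -0.045 (SE 0.05, M500) to 0.044 (SE 0.045, T1800), and for the retinoic acid hydroxylase Cyp26b1 from -0.3 (SE 0.12, T1800) to -0.034 (SE 0.11, P2500). Control replicates 02 and 06, with actin gaps above 1.4, both lay outside the range of the other controls for several of these genes. They measured 0.518 and 0.465 for Insl3 (others 1.202 to 1.35) and 1.73 and 1.909 for Cyp26b1 (others 1.168 to 1.318). Values for Cyp51 were 1.416 and 1.55 (others 1.082 to 1.146) and for Hsd3b1 1.689 and 1.579 (1.276 to 1.518). Those for Lhcgr were 0.671 and 0.662 (0.384 to 0.636) and for Por 0.445 and 0.339 (0.489 to 0.635). With array weights, the Cyp51 differences were -0.043 in T500 and -0.029 in T1800, against -0.17 and -0.14 with equal weights. The second probe set had the opposite sign for Cyp51 in M2000, for Lhcgr in P500 and T1800, for Por in M2000 and P2500, and for Cyp26b1 in T1800.

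Another 10 lists passed in none of the 7 contrasts with control by camera, with an estimated correlation or by fry. Their smallest camera adjusted p was 0.19 for retinoic acid genes, 0.34 for endoplasmic reticulum stress, 0.37 for heat shock and 0.32 for p53 response (all in P2500). It was 0.17 for androgen-responsive Sertoli genes (P500), 0.3 for Sertoli cell markers (M500), 0.43 for spermatogonia (T500), 0.12 for spermatocytes (M500), 0.16 for endothelium (P500) and 0.15 for erythrocytes (T500). In all, 22 of the 147 tests passed by camera, 20 higher and 2 lower, and 0 with an estimated correlation or by fry.

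At the matched dose of 500 ppm, no probe set differed between compounds with limma and equal weights. M500 against P500 had a smallest adjusted p of 0.16 with 2321 at an unadjusted p under 0.05 and 0 by array weights, M500 against T500 0.37 with 2077 and 0, and P500 against T500 0.37 with 1576 and 53. At equal weights without the 5 arrays of actin gap above 1.4, P500 against T500 had 676 calls, M500 against P500 11 and M500 against T500 0, and with the actin gap as a covariate M500 against P500 had 15 and the other two 0. None of the 5 arrays is in P500 or T500, so for that contrast they enter only through the shared estimate of spread, and the cause was not tested further. No list shift differed over all arrays (smallest adjusted p 0.36, 0.085 and 0.085). The 95% interval of M500 minus P500 was -0.025 to 0.17 for steroidogenesis and -0.16 to 0.21 for xenobiotic genes, that of M500 minus T500 -0.11 to 0.086 and -0.22 to 0.16, and that of P500 minus T500 -0.18 to 0.0058 and -0.23 to 0.11. Matrix genes stood at 0.509 ± 0.074 (SD, n = 4) in P500 and 0.71 ± 0.11 (n = 4) in T500, a difference of -0.2 (interval -0.36 to -0.046, adjusted p = 0.15). Intervals of this width leave shifts of that size between compounds open.

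The high doses differ in ppm. Arhgef28 was lower in M2000 (0.249 ± 0.04, SD, n = 5) than in T1800 (0.751 ± 0.18, n = 4) by a difference of -0.5 (SE 0.077, adjusted p = 0.017), the 1 probe set of that contrast to pass (1054 at an unadjusted p under 0.05, 634 by array weights). M2000 against P2500 gave 0 (smallest adjusted p 0.24, 831 at an unadjusted p under 0.05, 715 by array weights) and P2500 against T1800 gave 0 (0.11, 1951 and 1476). Without the 5 arrays of actin gap above 1.4, M2000 against T1800 gave 14, M2000 against P2500 280 and P2500 against T1800 349, but 3 of the 4 P2500 arrays then left are those with liver transcripts. Without these 3 arrays instead, M2000 against P2500 and P2500 against T1800 gave 0. No list shift differed at the high doses over all arrays (smallest adjusted p 0.085, 0.085 and 0.053), while over the comparisons at both dose levels 12 differed with the actin gap as a covariate and 17 without the 5 arrays. Xenobiotic genes stood at 0.592 ± 0.28 (n = 5) in P2500, 0.359 ± 0.016 (n = 5) in M2000 and 0.355 ± 0.026 (n = 4) in T1800, with the liver transcripts in 3 of the P2500 arrays. All 5 M2000 arrays belonged to the earlier animal series and 3 of the 4 T1800 arrays to the later one, and with a block for the series the difference was -0.47 (adjusted p = 0.39). The Arhgef28 call also ended when T1800 replicate 02 (adjusted p = 0.18) or 04 (0.25) or M2000 replicate 01 (0.052), 02 (0.07) or 04 (0.057) was left out.

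Between doses of 1 compound, Arhgef28 was higher in T1800 than in T500 (0.239 ± 0.061, SD, n = 4) by 0.51 (SE 0.081, adjusted p = 0.028), the 1 probe set to pass (612 at an unadjusted p under 0.05, 36 by array weights). All 4 T500 arrays belonged to the earlier animal series, and with a block for the series the difference was 0.481 (adjusted p = 0.78). The call also ended without any 1 of the 4 T500 arrays or without T1800 replicate 02, 04 or 05 (adjusted p 0.053 to 0.34). M2000 against M500 gave 0 with limma (smallest adjusted p 0.26, 2343 at an unadjusted p under 0.05, 13 by array weights) and P2500 against P500 gave 0 (0.15, 1190 and 855).

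Across 31042 probe sets, which are not independent replicates, differences from control correlated between M2000 and P2500 (Pearson's r 0.45, Spearman's rho 0.54), M2000 and T1800 (0.58, 0.56) and P2500 and T1800 (0.26, 0.35). Unchanged groups simulated against 1 shared base group gave a mean r of 0.42, 0.4 and 0.39. All simulated groups were drawn at random from the residuals of the 31 arrays, so the base was not the control arrays themselves. The covariances were 0.001, 0.0015 and 0.0011 against 0.0014, 0.0014 and 0.0013 in the simulation, and with the controls split the mean r was -0.17, -0.041 and -0.099. The correlations lay within the simulated ranges. Ranges this wide could hardly be exceeded, so the comparison neither shows nor excludes an effect common to the compounds. The 3 comparisons with control had no called probe set in common, since M2000 and P2500 had 0 calls.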

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

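Tests on liver markers were fixed before those markers were looked at; the tests on epididymis, degradation, presence in every animal, Alb and the first principal component were chosen after the result was seen. After a first run of the liver test, 5 markers listed as not looked at were moved to those looked at. Single arrays stood apart from the rest of their group in 12 of 96 values by group, where chance gives about 1 in 20, or 4.8. M2000 replicate 05 had an actin gap of 1.47 (others 0.831 to 0.946), a first-component value of 21 in size and a Cyp51 score of 1.62 (others 1.14 to 1.25). The slope over the hybridisation controls was 0.919 in Control replicate 02, 0.577 in M2000 replicate 01, 0.647 in P2500 replicate 01 and 0.587 in T500 replicate 01. Star measured 0.327 in P2500 replicate 05 (others 0.941 to 1.19), 0.909 in T500 replicate 04 and 0.58 in T1800 replicate 05, Cyp26b1 1.19 in T1800 replicate 03, and Arhgef28 0.149 in T500 replicate 03. Arhgef28 differed between groups by a test of the difference itself, by -0.5 in M2000 against T1800 and by 0.51 in T1800 against T500.

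Liver transcripts appeared in P2500 replicates 02, 03 and 04, whose median liver marker was 1.01, 0.979 and 0.949 against -0.176 to -0.0201 in control. RNA degradation was argued against, since 0 of the 3 arrays had an actin gap above 1.4. Epididymis tissue as the source was argued against, since 2 of its 11 markers were above all other 28 arrays in those 3. These were Adam7 (0.639, 0.574 and 0.555, highest other array 0.00607) and Rnase12. That count has limited weight, since other markers, such as Cst8 (2.47 ± 0.355 in control), were already high in control. The median liver marker lay above every control in 3 of 5 P2500 arrays. As the 3 were picked for this, it describes a rise not seen in every animal and tests no cause. RNA from liver in these preparations is a candidate explanation: of 30 markers not looked at before, 26 lay above the other 28 arrays in all 3, as did 17 of 17 looked at before, with 2 and 4 of them also in the fixed lists, while Sult2a1, Cyp7a1, A1bg and Ass1 did not. Smaller amounts of liver RNA may be present in other arrays, since Alb correlated with the median of the other markers over those 28 (r = 0.82, rho 0.85; permutation p = 1e-05 for both, the smallest possible, adjusted 1e-05 over 6 relations; r = 0.79 without the 2 arrays farthest out); group means of Alb were 1.04 in control, 1.58 in M2000 and 0.112 in P500. At what step liver RNA would have entered, and whether an effect of the compound in some animals raised these genes, was not tested.

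The first principal component may reflect RNA degradation: it correlated with the actin gap over 31 arrays (Pearson's r = 0.97, rho 0.91; permutation p = 1e-05 for both, the smallest possible, adjusted 1e-05). The value was 0.96 without the 2 arrays farthest out, 0.92 within the 26 arrays of a gap up to 1.4 and 0.97 within the earlier animal series. The GAPDH gap gave 0.93. Treatment group was argued against as its source, since 13.9% of its variance lay between groups (permutation p = 0.7). The slope over the hybridisation controls cannot be told apart from chance as a source: r was 0.44 (adjusted permutation p = 0.02), rho 0.083 (adjusted p = 0.7), and r -0.17 without the 2 arrays farthest out, so the relation rests on those arrays. No biological explanation for the component besides treatment group was tested.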

How the results depend on the processing

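Counts of called probe sets changed between settings, and the cause was not tested; contrasts are with control where no second group is given, and counts that differed from the first by no more than a factor of 1.5 are not all listed. With the scores as deposited, M500 had 6 calls, T1800 0, M500 against P500 1, M2000 against T1800 0, M2000 against M500 7 and T1800 against T500 0. Array median centring gave M500 1, T1800 1, M2000 against T1800 0 and T1800 against T500 0, and spike scaling by the hybridisation controls gave T1800 5 and P2500 against T1800 1. Probe sets above the median mean gave P2500 1 and T500 2, and trend and robust moderation P2500 2 and T500 1. With only the groups compared, P2500 had 1, T500 1, T1800 1 (a probe set other than the first 2), M500 against P500 2, M2000 against T1800 0, P2500 against T1800 1 and T1800 against T500 0. Limma arrayWeights gave 61 in M500, 8 in M2000, 17 in P500, 882 in P2500, 44 in T500, 264 in T1800, 294 in the mean of the 3 high-dose groups, 53 in P500 against T500, 715 in M2000 against P2500, 634 in M2000 against T1800, 1476 in P2500 against T1800, 13 in M2000 against M500, 855 in P2500 against P500 and 36 in T1800 against T500. The actin gap covariate gave M500 231, P2500 50, T1800 0, M500 against P500 15, P2500 against T1800 1, P2500 against P500 22 and T1800 against T500 2. Without the 5 arrays of actin gap above 1.4, M500 had 18, P500 198, P2500 308, T500 2, T1800 0, M500 against P500 11, P500 against T500 676, M2000 against P2500 280, M2000 against T1800 14, P2500 against T1800 349, M2000 against M500 1, P2500 against P500 426 and T1800 against T500 3.

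With a replicate block (same replicate numbers paired), M500 had 1, P2500 1, T500 1, T1800 1, M2000 against T1800 0, T1800 against T500 0 and the gene list tests 8. The numbers did not pair the animals: array profiles of the same number had a mean correlation of 0.027 over 73 pairs and those of different numbers 0.016 over 336. An animal series block gave T1800 2, of which 1 was among the first 2, M2000 against T1800 0, P2500 against T1800 1 and T1800 against T500 0. Only the earlier animal series, with a single T1800 array assumed to vary like the other groups, gave T1800 0, M2000 against T1800 2, P2500 against T1800 2, T1800 against T500 1 (not Arhgef28) and the gene list tests 4, and only the later one T1800 0.

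Gene list tests passed in 22 at first, in 0 with the correlation estimated for each list, in 0 by fry and in 7 without the 3 P2500 arrays with liver transcripts, 6 of them among the 22. They passed in 27 as deposited (21 among the 22), 28 with spike scaling (18), 25 with the mean over a gene's probe sets (21), 21 above the median mean (17), 21 with array weights (15), 18 with the animal series block (15), 21 with the actin gap covariate (16) and 21 without the 5 arrays (13). Adjusted p-values of lists that changed direction were 0.043 for spermatid markers in M2000 as deposited and 0.94 with array weights, and, without the 3 P2500 arrays, 0.9 for cholesterol, 0.58 for xenobiotic, 0.89 for fatty acid, 0.38 for fibroblast and 0.76 for adipocyte genes in P2500. The number of list shifts that differed between compounds, 0 at first, became 12 with the actin gap covariate and 17 without the 5 arrays of actin gap above 1.4. Correlations of effects with the controls split were -0.17 for M2000 and P2500, -0.041 for M2000 and T1800 and -0.099 for P2500 and T1800, and without the 3 P2500 arrays 0.01 for the first and -0.13 for the last. Without the 5 arrays of actin gap above 1.4 they were 0.33, 0.27 and 0.13, and as deposited 0.71, 0.66 and 0.49.

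Leaving out each array in turn gave 0 to 156 calls in M500 (highest without M500 replicate 01), 0 in M2000 and P500, 0 to 283 in P2500 (without P2500 replicate 05), 0 to 3 in T500, 0 to 5 in T1800 and 0 to 1 in the mean of the high doses. It gave 0 to 19 in M500 against P500, 0 to 5 in M500 against T500 and 0 to 35 in M2000 against M500, each highest without M500 replicate 01. Ranges were 0 to 228 in M2000 against P2500 and 0 to 242 in P2500 against P500, highest without P2500 replicate 05, 0 to 246 in P2500 against T1800 (without P2500 replicate 01), 0 to 2 in M2000 against T1800 and T1800 against T500, and 0 in P500 against T500. Gene list tests passed in 14 (without Control replicate 06) to 26. Without T1800 replicate 02 or 04, or without Control replicate 02, 04, 05 or 06, T1800 had 0 calls. Settings with all 34 arrays and with pseudocounts were not run, since 3 arrays had no values and the scores are not linear.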

Other observations

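The tests of the animal series, of degradation on the matrix list and of list and between-group splits were fixed before their results were seen; those of germ cells, of degradation on the other 2 lists, of the animal series on each list alone, of splits with control and of all array-weighted splits were chosen after. Of the members of the NRF2 and antioxidant list, which passed in P2500 alone, 3 are given with values that did not pass over all probe sets. Gpx3, a glutathione peroxidase, measured 0.181 ± 0.12 (SD, n = 5) in P2500, 0.222 ± 0.074 (n = 4) in T500 and 0.242 ± 0.068 (n = 4) in T1800 against 0.0345 ± 0.061 (n = 6) in control (adjusted p = 0.45, 0.52 and 0.36). Gpx1 measured 0.967 ± 0.29, 0.919 ± 0.11 and 0.881 ± 0.061 against 0.636 ± 0.16 (adjusted p = 0.13, 0.56 and 0.77). The cystine transporter Slc7a11 measured 0.481 ± 0.12 in T1800 against 0.252 ± 0.07 (adjusted p = 0.54).

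Acadl, a dehydrogenase of long-chain fatty acids, measured 1.2 ± 0.067 (SD, n = 4) in T500 and 1.22 ± 0.12 (n = 4) in T1800 against 0.91 ± 0.18 (n = 6) in control (adjusted p = 0.52 and 0.22), and Fabp3, a fatty acid carrier, 2.07 ± 0.18 in T1800 against 1.68 ± 0.27 (adjusted p = 0.73). The fatty acid oxidation list passed by camera in neither T500 nor T1800. The beta-globin gene Hbb measured 1.84 ± 0.24 in T500 and 1.66 ± 0.13 in T1800 against 1.13 ± 0.38 (adjusted p = 0.52 and 0.77), and the erythrocyte list shifted by 0.16 (SE 0.042) and 0.12 (SE 0.042) with camera adjusted p-values of 0.15 and 0.28. In T1800 the erythrocyte shift was 0.066 with the actin gap as a covariate and 0.074 without the 5 arrays of actin gap above 1.4. The mean actin gap was 0.79 in T500 and 0.852 in T1800 against 1.12 in control.

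The matrix, macrophage and steroidogenesis lists rose together in T1800. For the matrix list, RNA degradation was argued against (shift 0.23 with the actin gap as a covariate, SE 0.075, interval 0.08 to 0.39). So was the animal series as its only source (shift 0.21 within the later series, SE 0.02, interval 0.16 to 0.27, n = 3 and 3). For both, the list was picked for its shift in these same arrays, so the sizes and intervals are no independent estimates. They show only that the shift did not go away in these settings. As for a lower share of germ cells, the matrix list exceeded the Sertoli list by 0.2 (SE 0.072, interval 0.056 to 0.35). That gap does not decide it, since the matrix list was picked for its shift. The Sertoli list shifted by 0.0073 (SE 0.014), spermatocytes by -0.04 (SE 0.032) and spermatids by 0.064 (SE 0.042). Other changes of cell composition were not tested. For the steroidogenesis and macrophage lists, degradation (0.071, interval -0.011 to 0.15, and 0.024, interval -0.027 to 0.075) and the animal series (0.12, interval -0.025 to 0.26, and 0.051, interval -0.07 to 0.17) cannot be told apart from an effect of treatment, since each interval holds 0, although with the covariate both still passed camera (adjusted p = 0.023 and 0.0069) and 3 of 3 lists had shifts within the later series near the pooled ones. Splits scored on these 3 lists alone (2 of 100 as small as the real camera p of 3.7e-06, smallest other 1.2e-06) decide nothing about chance, since the lists were picked for passing, whereas over all 21 lists 3 of 100 splits reached the real count of 4. An effect of triadimefon on matrix genes may remain as a hypothesis, though with an estimated correlation no list passed.

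Other splits of the same arrays were counted for every contrast with limma and equal weights. For T1800 against control, 4 of 100 splits called at least the real 2 (highest other 5). For M2000 against T1800 3 of 100 called at least the real 1 (highest other 2). For T1800 against T500 it was 1 of 35 (real 1, highest other 0), the smallest share possible. Few splits thus reached the real counts, but chance cannot be excluded, since of the 16 contrasts these 3 were taken for having calls. The 3 also share the same T1800 arrays, and the splits took no account of the animal series. With a block for the series the differences of Arhgef28 in M2000 against T1800 and T1800 against T500 were -0.47 and 0.481. They were near the -0.5 and 0.51 without it, and both calls ended. A real count of 0 is reached by every split, so the other contrasts hold no test of chance, and only their highest other count is informative. With control it was 13732 for M500 (84 of 84 splits), and, each with 100 of 100, 3430 for M2000, 800 for P500, 9305 for P2500, 16 for T500 and 2351 for the mean of the high doses. Between groups it was 0 for M500 against P500, 50 for M500 against T500 and 1 for P500 against T500 (35 of 35 each), 221 for M2000 against P2500, 266 for P2500 against T1800 and 284 for P2500 against P500 (100 of 100 each), and 1 for M2000 against M500 (56 of 56). Splits that called far more probe sets than the real one point to a structure of the samples other than the groups.

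With array weights, chance cannot be excluded for M500 (25 of 84 splits as large; real 61, highest other 11315), M2000 (11 of 100; 8, 7829), P500 (21; 17, 7614), P2500 (13; 882, 9029), T500 (19; 44, 3038), T1800 (7; 264, 567) and the mean of the high doses (6; 294, 6253) against control. The same held for P500 against T500 (2 of 35; 53, 108), M2000 against P2500 (9 of 100; 715, 4018), M2000 against M500 (14 of 56; 13, 5981), P2500 against P500 (17 of 100; 855, 5456) and T1800 against T500 (3 of 35; 36, 57). Few splits were as large for M2000 against T1800 (1 of 100, real 634, highest other 503) and P2500 against T1800 (2 of 100, 1476 and 1601). Chance cannot be excluded there either, since these contrasts were taken from 16 for their small shares. Nor do these counts separate a treatment from the animal series. All M2000 and P2500 arrays are of the earlier series, 3 of 4 T1800 arrays are of the later, and the splits ignore it. In P2500, 3 arrays carry liver transcripts. On simulated data of T1800 against control, array weights gave 5543 false of 6501 calls, 5439 of them in 1 of 5 data sets. List counts were adjusted here over the 21 lists of 1 contrast. Few splits were as large for P2500 (4 of 100, real 8, highest other 9), T1800 (3 of 100, 4 and 5) and the mean of the high doses (2 of 100, 8 and 10). For P500 there were 7 of 100 (3 and 3). Over the 7 contrasts with control, chance cannot be excluded for any of these. With an estimated correlation and by fry 0 lists pass in each of them. All 8 lists of P2500 end without the 3 arrays with liver transcripts, though for lists other than xenobiotic metabolism lost precision could account for that. Real counts of 0 held no test of chance here either: M500 against P500 and T500 with array weights (35 of 35 each, highest other 3922 and 1835), and the lists in M500 (84 of 84, highest other 2), M2000 (100 of 100, 3) and T500 (100 of 100, 4). The epididymis call in M500 and the spermatid call in M2000 thus end when adjusted over the 21 lists of their contrast. Here too, splits that called several times the real count point to a structure of the samples.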
